A study of Oryzias latipes with 2 samples.

How the data were processed

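Skin and scales of adult male and female medaka (Oryzias latipes, the HdrR inbred strain) were dissociated with TrypLE, a trypsin-like enzyme mix, at 37 °C for 1 h, per the labels' protocols. Nuclei were stained with Draq5 and cells were sorted, and per the series' design text the sort enriched pigment cells by their GFP and mCherry signals; the gates are not given in the sources used here. Per the labels' protocols, 2 loadings on the 10x Genomics droplet platform aimed at 10000 and 1000 cells, and libraries of transcript 3′ ends were sequenced to a target of about 25000 reads per cell. The libraries are called run 1 and run 2 here. Both carry the same labels, so they form 1 group of 2 libraries, and nothing in the labels says that they came from separate animals.

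The authors deposited, for each run, a matrix of counts of unique molecular identifiers (UMIs), each count standing for 1 captured transcript molecule, per gene and cell barcode. Per the submitters' processing notes and the file headers, the matrices came from Cell Ranger 7.1.0. The genome build and the annotation are not given in the sources used here. The matrices list 23601 features, of which 13522 carry a gene symbol, 10078 only an Ensembl identifier, and 1, pnp4a, a name without an Ensembl identifier. The table of RefSeq genes at hand matched 0 features by Ensembl identifier, so gene names are those of the deposited files and features without a symbol are not named. No cell type annotation was used from elsewhere. Genes with near-identical copies may share reads, and their counts are uncertain to that extent; features that share a symbol are told apart by their identifier.

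Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 20% of UMIs from the 13 mitochondrial features. This kept 4503 of 4702 barcodes in run 1 and 577 of 614 in run 2. Scrublet's method was applied to each run; its automatic threshold called 14 and 1 doublets, below 0.5% of the barcodes, so the fixed fallback was used and barcodes above the top 4% of scores were removed, 156 and 21. The 4903 cells left, 4347 from run 1 and 556 from run 2, were scaled to 10000 counts per cell, log-transformed, and reduced to 2000 variable genes chosen with the run as batch. The 515 features of the 16 fixed pathway lists and the mitochondrial features were held out of the variable genes, so that pathway genes did not shape the clusters. Clusters came from 30 principal components, 15 nearest neighbours and the Leiden algorithm at resolution 1, with no integration of the runs (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, python 3.11.15).

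Clusters were named from markers of 20 classes fixed before the data were examined (263 symbols, 153 of them matched). A marker counted where at least 10% of a cluster's cells held a UMI and the level was at least 2-fold the median over clusters. Among classes with at least 3 such markers, the class with the highest mean log2 ratio to that median (10 CPM added) gave the name. A cluster stayed unnamed where its 10 leading genes held more markers of another class, where they went against the name, or where its median UMI count was under 1/3 of that of its runs with no marker of the name among its leading genes. These scoring thresholds were set after the data were seen. Of 29 clusters, 5 stayed unnamed; they held 6.42% of the cells of run 1 and 10.3% of those of run 2.

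UMI counts were summed per run and class. The planned comparisons set leucophore-like cells against iridophore-like, xanthophore-like and melanophore-like cells, and iridophore-like against xanthophore-like cells, with sums of at least 10 cells in both runs. Only leucophore-like and xanthophore-like cells met this. Their comparison used edgeR 4.0.16's quasi-likelihood test (R 4.3.3, limma 3.58.1) with TMM scaling, filterByExpr, the run as a block and the iridophore-like sum of run 1 in the fit, which leaves 1 residual degree of freedom over 5 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The SE printed with a log2 fold change is its absolute value divided by the square root of the test's F statistic. It is not a separately fitted error. Where a class had 0 UMIs, the log2 fold change depends on a small added count, and its SE does not measure how precisely the size is known. Because only xanthophore-like cells could be tested, the planned comparison with the mean of the other pigment classes is the same test. Gene lists were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 16 lists, and again with an estimated correlation. The comparisons with iridophore-like cells rest on 1 sum of that class, in run 1; for these, each gene's UMIs scaled to the total of its sum (CPM) with exact Poisson intervals and ratios with exact intervals are given, with no test. There, a list's median log2 ratio used CPM plus 10, over genes whose higher level would give at least 10 UMIs in the shallower sum, and its percentile came from 10000 random lists of the same size matched on mean expression. A comparison of leucophore-like with 5 non-pigment classes in the same kind of fit was added after the data were seen.

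Named genes follow a rule written before the data were examined: of each list, up to 4 called members with the largest change in the same direction in both runs; the 8 called genes with the largest change each way that have a symbol, did not serve for clustering and are not markers; and pnp4a, XDH, gch2, gart, paics, uox, aox5 and GPNMB whatever their result. No feature of the files matched aox5. In the comparison with iridophore-like cells, where nothing can be called, the same rule was applied to genes at least 2-fold apart from both leucophore-like sums. Any other gene named was chosen after its values were seen, and the text says so beside it or gives it as part of a cluster's definition.

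Both edgeR comparisons were tested on simulated data with 100 genes changed at each of 2 sizes. Counts were drawn from 1 pooled profile for all classes, at the sizes of the real class sums, with a dispersion of 0.1. The profile holds no run effect and no class difference besides the changed genes. The dispersion fitted to leucophore-like minus xanthophore-like was 0.134. The rates below may thus differ from those in the real sums. For leucophore-like minus xanthophore-like, over 2844 genes tested, 1 of 53 tested genes changed 2-fold was recovered, and 33 of 76 changed 4-fold, with 1 false call. For leucophore-like minus non-pigment classes, over 2212 genes, 14 of 49 changed 2-fold and 65 of 68 changed 4-fold were recovered, with 4 false calls. The exact interval of a run 1 ratio held the simulated ratio for 96 of 100 genes changed 2-fold against iridophore-like cells (998 genes eligible) and 99 of 100 against xanthophore-like cells (2132 eligible), and for 96 of 100 in each at 4-fold.

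Alternatives tried were size factors by the median of ratios, DESeq2 1.42.0, no filter on low counts, no run block, all classes in one fit, other clustering resolutions, pathway lists left among the clustering genes, doublets kept, a minimum of 1000 UMIs, centring of each run before clustering, a minimum of 20 cells per sum, and leaving out single sums. Intervals and floors cover counting error only. A floor is the level of 3 UMIs. Where a class had 0 UMIs, a fold given as at least some value sets the other level against that floor. Such a fold leaves out the counting error of the other level, so the exact lower limit is smaller. For tppp3 within run 1, leucophore-like against xanthophore-like, it is 711 in place of 913. At the depth of the sums, 10 UMIs equal 61.9 CPM in leucophore-like cells of run 1, 3.81 CPM in run 2, 0.972 CPM in xanthophore-like cells and 131 CPM in iridophore-like cells of run 1. Not reported are a test against iridophore-like or melanophore-like cells, for want of a sum in both runs, and shares of cells compared between runs, since each run is 1 sorted library.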

Results

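The data are single-cell transcriptomes of skin and scale cells from adult medaka, sorted to enrich pigment cells. The title of the study concerns the light-scattering particles of leucophores, the white pigment cells of this fish. Leucophores share the skin with xanthophores, which hold yellow to orange pteridine and carotenoid pigment, with iridophores, which hold reflecting guanine crystals, and with melanophores, which hold melanin. The labels name 1 group with 2 libraries. Run 1 held 4702 barcodes and 25236411 UMIs, with a median of 4044 UMIs per barcode, and run 2 held 614 barcodes and 6946744 UMIs, with a median of 8861. After filtering and removal of likely doublets, 4347 and 556 cells were analysed. No library serves as an untreated control, so keratinocyte-like cells of the same libraries give the background level of each pigment gene.

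Of the 29 clusters, 1 was leucophore-like, 4 were xanthophore-like and 1 was iridophore-like, and none was melanophore-like. The leucophore-like cluster met 4 of 5 leucophore markers, the glucose transporter genes slc2a15a and slc2a15b and the paired box genes pax3b and pax7a. The xanthophore-like clusters met the same 4, with 5 of 7 xanthophore markers besides (csf1ra, scarb1, plin6, sox5 and slc2a11b), and csf1ra stood as high in the leucophore-like cluster, at 684 CPM. The leucophore name thus also rests on the low levels of the other 4, at 8.26, 2.51, 1.44 and 21.9 CPM for scarb1, plin6, sox5 and slc2a11b in that cluster. scarb1, a lipoprotein receptor needed for carotenoid uptake, stood at 37.1 and 6.48 CPM in leucophore-like cells of runs 1 and 2 against 1628 CPM in xanthophore-like cells of run 1. Of the leucophore markers, pax7a stood at 1362 and 1961 CPM in leucophore-like cells against 986 CPM in those xanthophore-like cells, and slc2a15b at 272 and 355 against 312 CPM. The others were lower in leucophore-like cells. pax3b stood at 18.6 and 27.8 CPM against 209 CPM there. slc2a15a stood at 30.9 and 54.1 CPM against 69.8 CPM there and 1322 CPM in iridophore-like cells of run 1. The iridophore-like cluster met 4 of 7 iridophore markers (FHL3, ltk, tfec and alx4b), and GPNMB, pnp4a and apoda.1 were among its leading genes. It also met 3 leucophore markers. The leucophore-like cluster met 4 markers of the melanophore list as well, and each xanthophore-like cluster met 5. In each of these clusters the class that gave the name had the higher score.

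The pigment classes lay almost wholly in different runs. Xanthophore-like cells made up 2222 cells of run 1, or 51.1% (exact binomial 95% interval 49.6 to 52.6%), and 12 cells of run 2, or 2.16% (1.12 to 3.74%). Leucophore-like cells made up 25 cells of run 1, or 0.575% (0.373 to 0.848%), and 217 cells of run 2, or 39.0% (35.0 to 43.2%). Iridophore-like cells numbered 29 in run 1, or 0.667% (0.447 to 0.957%), and 1 in run 2. No cell of either run fell in a cluster named melanophore-like, which is an outcome of the naming and sets no upper limit, as 8 cells of run 2 with melanosome genes lay in another class. Keratinocyte-like cells made up 20.1% and 29.3%, and fibroblast-like cells 5.04% and 4.68%; T or NK cell-like cells numbered 521 and 31. Each run is 1 sorted library with its own target and depth, and the gates are not given; any of these can set the shares, so no test was made between runs. The intervals cover counting error only.

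**Figure D1:**
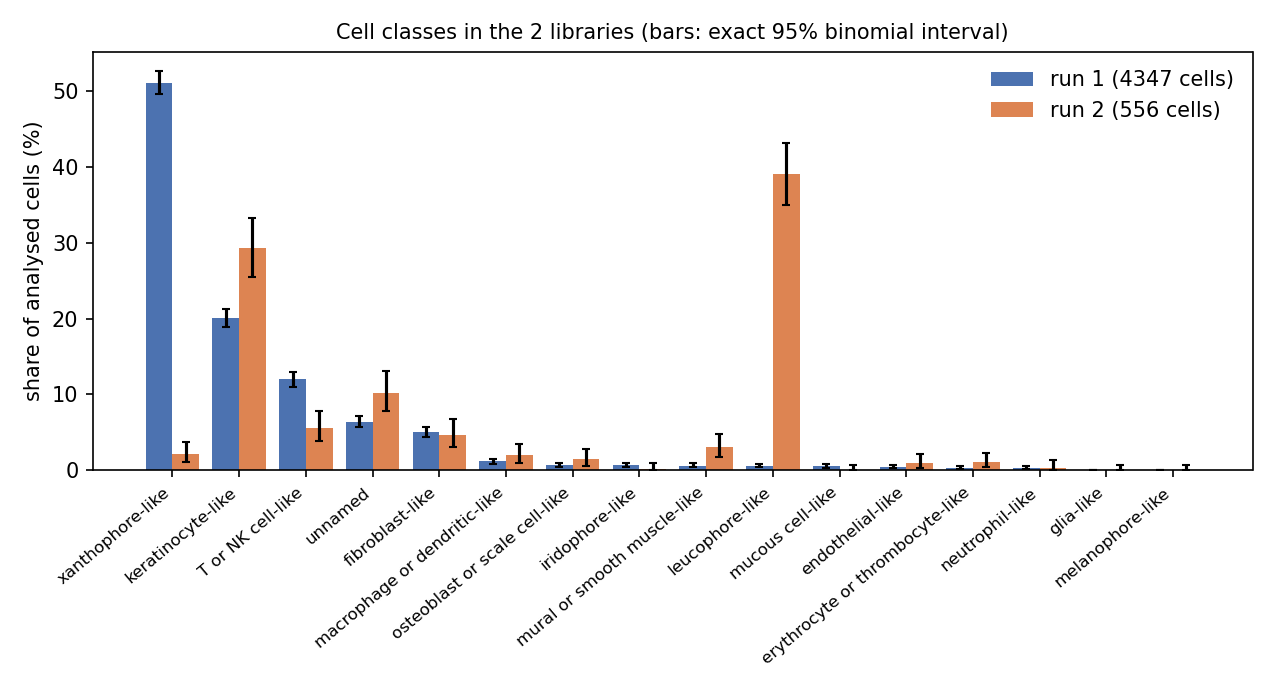
Share of analysed cells (percent, vertical axis) in each cell class (horizontal axis) for run 1 (4347 cells, blue) and run 2 (556 cells, orange), with exact 95% binomial intervals as error bars. Xanthophore-like cells lead run 1 at 51.1%, and leucophore-like cells lead run 2 at 39.0%.

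The first comparison asks what sets leucophore-like cells apart from xanthophore-like cells, the other pteridine-bearing class. Of 6 genes tested that salvage or degrade purines, 4 were higher in leucophore-like cells, although the list as a whole was not past the threshold with an estimated correlation between genes (camera, Benjamini-Hochberg adjusted p = 0.870). Among these, gda, guanine deaminase, which turns guanine into xanthine, stood at 136 and 271 CPM in the leucophore-like sums of runs 1 and 2 and at 0.0972 and 0 CPM in the xanthophore-like sums (log2 fold change 9.96, SE 1.07). In keratinocyte-like cells gda stood at 1.62 and 2.16 CPM. Among transporters, slc23a4, of the nucleobase and ascorbate transporter family, stood at 2036 and 2024 CPM against 62.6 and 63.0 CPM (log2 fold change 5.21, SE 0.66), with 2.08 and 1.44 CPM in keratinocyte-like cells. In the other direction, spra, sepiapterin reductase of pteridine synthesis, was lower, at 37.1 and 6.86 CPM against 580 and 75.6 CPM (log2 fold change −3.50, SE 0.65). Across all genes, 225 were higher and 316 lower in leucophore-like cells of 3636 tested, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 222 and 295 went the same way within both runs, which is no separate check, as the calls used the same sums.

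The xanthophore-like sum of run 2 limits this test. Of its 12 cells, 8 held UMIs of pmela, a melanosome gene, and these gave 59.0% of the sum's UMIs, against 2 of 2222 xanthophore-like cells of run 1. Without that sum, in a fit of all classes chosen after the data were seen, 255 genes were higher and 348 lower, and 141 of the 216 higher genes and 165 of the 224 lower genes tested in both were called again. Among genes tested in both, much of that loss comes with the change of fit. With the sum kept, the fit of all classes called 164 of 216 higher and 217 of 280 lower genes again. Without the sum, fewer of the 316 lower genes were tested at all, 224 against 280, and these shares leave the untested ones out. Of the 34 called genes named here, 26 were tested in that fit and 18 called. Within run 1 alone, 220 of the 225 higher and 284 of the 316 lower genes were at least 2-fold apart in the same direction. The calls themselves drew on these sums of run 1, so this is no independent support for them. Nothing in the labels says that the runs came from separate animals, so no p-value here measures a spread between animals. With the run as a block, this test had 1 residual degree of freedom. Its spread was thus mostly borrowed across genes of these libraries rather than measured for each gene.

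Of the 6 purine salvage and degradation genes, 4 were higher and none lower (5 and 0 adjusted over the list alone), with a median log2 fold change of 2.20. That median was 1.93 with no replicate block and 0.04 over the 26 members tested without a filter. The count fell to 1 with no replicate block, without a filter or with centred runs, and to 2 without either leucophore-like sum in the fit of all classes. By limma's camera the list rose with a Benjamini-Hochberg adjusted p of 0.00491, but adjusted p = 0.870 with an estimated correlation, and 0.0573 without the xanthophore-like sum of run 2. Besides gda, these were uraha, which acts in urate breakdown, and the purine nucleoside phosphorylase genes pnp4a and pnp5a. uraha stood at 1764 and 2139 CPM against 884 and 265 CPM, with between 10.8 and 15.7 CPM (exact Poisson interval) in keratinocyte-like cells of run 1 and 3.97 CPM in those of run 2. pnp5a stood at 130 and 166 CPM against 56.4 and 0 CPM. pnp4a stood at 68.1 and 56.4 CPM against 3.30 CPM in run 1, while in run 2 the xanthophore-like sum held 5 UMIs, or 63.0 CPM, all in the cells with pmela. In run 1 the ratio was 20.6 for pnp4a (exact interval 9.42 to 41.7) and 2.31 for pnp5a (1.42 to 3.56), and the exact interval for uraha ran from 1.77 to 2.25. Without the xanthophore-like sum of run 2, gda and pnp4a were called again, while uraha went from a log2 fold change of 2.17 (SE 0.60) to 1.45 (SE 0.71) and pnp5a from 2.23 (SE 0.68) to 0.82 (SE 0.74), neither called. Neither XDH, xanthine dehydrogenase, nor uox, urate oxidase, passed the filter on low counts. XDH stood at 0 and 5.34 CPM in leucophore-like cells against 59.2 CPM in xanthophore-like cells of run 1, and uox at 0 against 0.389 CPM.

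Purine synthesis itself showed no called gene. None of 11 tested members of the de novo list was called (0 and 0 adjusted over the list alone), with a median log2 fold change of 0.34. paics, a bifunctional enzyme in the middle of that pathway, stood at 458 and 582 CPM against 386 and 227 CPM (log2 fold change 1.00, SE 0.56; edgeR Benjamini-Hochberg adjusted p = 0.274). gart did not pass the filter, at 12.4 and 6.10 CPM against 16.9 CPM in xanthophore-like cells of run 1. gcshb, of the glycine cleavage system, was the 1 higher gene among 7 tested for one-carbon supply, at 111 and 78.5 CPM against 2.72 and 0 CPM; the list alone also gave 1 lower gene.

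In pteridine synthesis, spra was the 1 called gene of 6 tested (1 higher and 1 lower adjusted over the list alone), and the list's median was −0.54. Without the xanthophore-like sum of run 2, 2 of 6 were lower with all classes (median −0.98) and 4 of 8 with no replicate block (median −0.78). gch2, GTP cyclohydrolase, the entry enzyme of pteridine synthesis, was abundant in both classes, at 3943 and 3056 CPM in leucophore-like and 2343 and 743 CPM in xanthophore-like cells, against 19.7 and 7.57 CPM in keratinocyte-like cells. Its log2 fold change of 1.61 (SE 0.61) missed the threshold with an edgeR Benjamini-Hochberg adjusted p of 0.0531. All 59 gch2 UMIs of the xanthophore-like sum of run 2 lay in 2 cells (4 and 55 UMIs), while the 8 cells with pmela held 0. The 743 CPM is thus lowered by cells without gch2. In run 1 the ratio was 1.68 (exact interval 1.55 to 1.82), and the log2 fold change within run 1 was 0.80. Without that sum of run 2, in the fit of all classes, the log2 fold change was 1.66 (SE 0.72), not called. This is larger than the gap within run 1, so it is no separate support for that ratio. The fit includes the non-pigment classes, whose mean gch2 level was 77.8 CPM in run 1 and 6.30 CPM in run 2. Whether this sets the larger size was not tested. spra was 15.6-fold lower in run 1 (exact interval 7.17 to 42.6), and it is also a leading gene of 1 of the xanthophore-like clusters, although it was held out of clustering.

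Regulators of the neural crest lineage went both ways, with 4 of 9 tested higher and 2 lower, overall and adjusted over the list alone. With no replicate block 1 was higher and 2 were lower, and the same counts came of the 24 tested without a filter. The transcription factor gene tfap2a had 0 UMIs in both leucophore-like sums and stood at 340 and 239 CPM in the xanthophore-like sums, at least 18.3-fold and 209-fold lower in leucophore-like cells when set against 3 UMIs within each run. Keratinocyte-like cells held tfap2a at 162 and 146 CPM. sox10 was lower, at 80.5 and 76.2 CPM against 1285 and 315 CPM (log2 fold change −2.74, SE 0.59). sox9a was higher, at 24.8 and 13.3 CPM against 0.0972 and 0 CPM, and so was id2a, at 142 and 144 CPM against 36.9 and 0 CPM. For sox9a the level of 24.8 CPM was 4 UMIs. Keratinocyte-like cells held sox9a at 11.9 and 31.4 CPM and iridophore-like cells of run 1 at 65.5 CPM, so it was low in xanthophore-like cells rather than particular to leucophore-like cells. Without the xanthophore-like sum of run 2, id2a was no longer called, its log2 fold change going from 2.71 (SE 0.72) to 1.40 (SE 0.63), and the other 3 were.

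Of 22 genes for lysosome-related organelles, the compartment class that includes pigment organelles, 2 were higher and none lower, overall and adjusted over the list alone. With no replicate block 1 was higher, as was 1 of 44 tested without a filter. The Rab GTPase gene RAB38 (ENSORLG00000004499) stood at 130 and 46.1 CPM against 1.85 and 12.6 CPM, and LYST at 458 and 341 CPM against 159 and 113 CPM. LYST was not called without the xanthophore-like sum of run 2, where its log2 fold change went from 1.76 (SE 0.55) to 1.28 (SE 0.65). GPNMB was at or under the floor in both classes, with 1 UMI in all of their sums. Among lysosomal hydrolases, ctsk, cathepsin K, was lower, at 0 and 1.52 CPM against 105 and 239 CPM, the 1 called gene of 15. H6PD was lower at 0 and 1.52 CPM against 135 and 37.8 CPM, the 1 called gene of 4 in the pentose phosphate list. Of 6 genes for nucleobase and urate transport, slc23a4 was called (2 higher and 1 lower adjusted over the list alone), with a median of 1.29, or 1.46 with the gene absent from 1 class at its bound. That median was 0.75 with no replicate block and −0.34 over the 16 members tested without a filter.

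The 6 called members of the cell cycle list, of 8 tested, were lower (7 adjusted over the list alone), with a camera adjusted p of 0.0136 after Benjamini-Hochberg adjustment, and adjusted p = 0.870 with an estimated correlation. The median of all 8 was −7.29, and −4.54 with the genes absent from leucophore-like cells at their bound. This call rests on 1 xanthophore-like cell of run 2 with 12408 UMIs, which held all 15 top2a and 16 mki67 UMIs of its sum; top2a stood at 0.486 and mki67 at 2.23 CPM in xanthophore-like cells of run 1. Without that sum, in the fit of all classes, the adjusted p by camera was 0.942, and top2a went from a log2 fold change of −11.52 (SE 1.99) to −1.50 (SE 1.86) and mki67 from −8.45 (SE 1.58) to −1.05 (SE 1.47), neither called. The called genes nusap1, rrm1 and cks2 had levels of 1.36, 2.43 and 1.65 CPM in xanthophore-like cells of run 1, and the same cell held all 11 UMIs of ddx4, a germ cell gene, in its sum.

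Of the largest changes outside the lists, the higher genes were nearly silent in xanthophore-like cells. tppp3, a tubulin-binding protein gene, stood at 266 and 132 CPM in leucophore-like cells against 0 UMIs (at least 913-fold within run 1 and 3.49-fold within run 2), tnfaip8l3 at 74.3 and 78.5 CPM against 0 UMIs (255-fold and 2.08-fold) and stum at 43.3 and 33.9 CPM against 0 UMIs (149-fold in run 1, with no bound above the floor in run 2). cax1, a leading gene of the cluster, stood at 334 and 470 CPM against 0.194 and 0 CPM. sema3ab, rgra and pacsin1a had 1 UMI each in the xanthophore-like sums and stood at 118, 86.7 and 74.3 CPM in leucophore-like cells of run 1. Lower genes with 0 UMIs in leucophore-like cells were dgat2, tfa, hsc70 and smc4. dgat2, which completes triglyceride synthesis, stood at 447 and 113 CPM (at least 24.1-fold within run 1 and 99.1-fold within run 2). The transferrin gene tfa stood at 74.7 and 126 CPM (4.02-fold and 110-fold). hsc70 stood at 41.5 and 126 CPM (2.23-fold and 110-fold) and smc4 at 26.2 and 151 CPM (1.41-fold and 132-fold). In run 2 these levels were 9, 10, 10 and 12 UMIs of the xanthophore-like sum of 12 cells, 8 of them with pmela. In the fit of all classes without that sum, tfa and hsc70 were not tested, nor were stum and pacsin1a.

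The other lists gave few calls against xanthophore-like cells in the planned fit. Of 60 oxidative phosphorylation genes, atp5if1b was the 1 called (0 adjusted over the list alone), with a log2 fold change of 1.53, and of 16 immediate early and heat shock genes klf6a was the 1 called (0 adjusted over the list alone), at 1.54. Neither was called without the xanthophore-like sum of run 2, where atp5if1b stood at 1.04 (SE 0.61, against 0.54 before) and klf6a was about as large, at 1.49 (SE 0.62, against 0.55). There other immediate early genes were called lower, 5 of 19 tested with all classes and 10 of 20 with no replicate block. No gene was called of 6 for glycolysis, 10 for pigment organelle transport, 13 for the vacuolar ATPase or 73 cytosolic ribosomal protein genes in the planned fit, overall or adjusted over the list alone, with median log2 fold changes of −0.37, 0.04, 0.46 and −0.04. Without that sum, with all classes, 1 transport gene and 2 ribosomal protein genes were called lower, the latter list with a median of −0.67. With no replicate block as well, 3 transport and 2 ribosomal protein genes (median −0.50) were lower, 5 oxidative phosphorylation genes and 1 of the vacuolar ATPase higher, and 1 glycolysis gene went each way. In the self-test, drawn from 1 pooled profile at these library sizes, 1 of 53 genes changed 2-fold was recovered. Changes of that size may thus mostly have been out of reach.

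**Figure D2:**
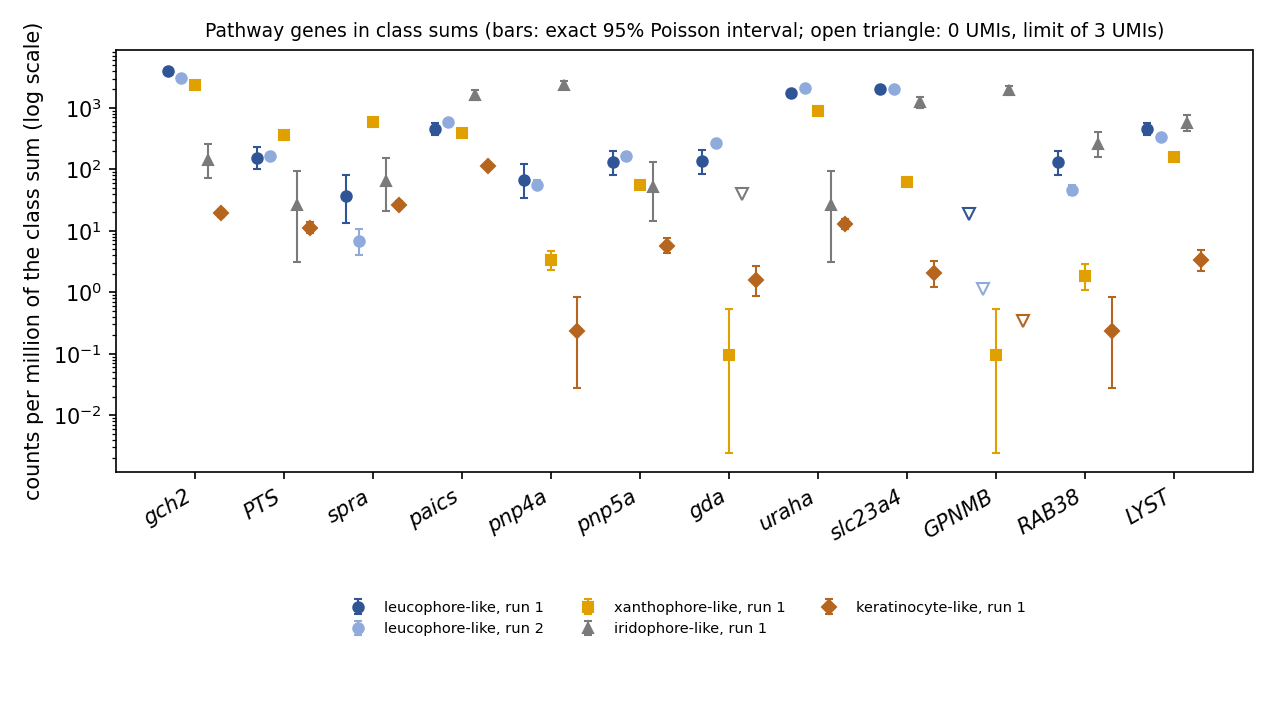
Level of 12 pathway genes (horizontal axis) in CPM on a log scale (vertical axis) in the class sums named in the key, with exact 95% Poisson intervals as error bars and open triangles at the level of 3 UMIs where no UMI was seen. gch2 and uraha are higher in both leucophore-like and xanthophore-like cells than in iridophore-like cells, and pnp4a and GPNMB are highest in iridophore-like cells at 2344 and 1938 CPM.

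The second comparison sets leucophore-like against iridophore-like cells, the class with guanine crystals, and asks how far they share purine and pteridine genes. It has no replicate check, as iridophore-like cells formed a sum in run 1 only, of 29 cells and 76375 UMIs; the values compare these libraries and their intervals cover counting error only. pnp4a was 34.4-fold lower in leucophore-like cells of run 1 (exact interval 18.8 to 70.2), at 68.1 against 2344 CPM, and was 56.4 CPM in run 2. uraha lay the other way, at 1764 and 2139 CPM against 26.2 CPM, a ratio of 67.4 in run 1 (18.5 to 559). gda stood at 136 and 271 CPM against 0 UMIs, 3.47-fold higher in run 1 when set against 3 UMIs (exact lower limit 2.59). gch2 was 27.4-fold higher (15.2 to 55.1), at 3943 CPM against 144 CPM.

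Of purine synthesis, single genes had lower levels in leucophore-like cells while the list did not stand apart. paics stood at 458 and 582 CPM against 1637 CPM, 3.57-fold lower in run 1 (2.66 to 4.83), and ppat, the committed step, at 18.6 and 39.3 CPM against 196 CPM, where 18.6 CPM is 3 UMIs (10.6-fold, 2.99 to 57.0). PRPS2 stood at 86.7 and 97.2 CPM against 196 CPM. The median of the 5 de novo genes with enough UMIs was −1.09 in log2 (−1.89 to −0.30), at percentile 21.01 of random lists. gart had too few UMIs to compare, at 12.4 against 39.3 CPM, as did XDH at 0 in run 1 in both classes and uox, with 0 UMIs in both. The 3 salvage genes, uraha, gda and pnp4a, had a median of 3.87 (percentile 97.9) although they went both ways. That median is the value of gda alone, which stands against 0 UMIs and depends on the 10 CPM added. For gda only a lower limit of the ratio is known, 3.47 against 3 UMIs and 2.59 by the exact interval. Neither the median nor its percentile thus measures the list. The 3 pteridine genes had a median of 2.19 (percentile 96.5), with PTS at 155 and 167 CPM against 26.2 CPM.

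GPNMB, a melanosome and lysosome glycoprotein gene, had 0 UMIs in leucophore-like cells of both runs against 1938 CPM. Set against 3 UMIs it was 104-fold lower in run 1 (exact lower limit 83.8). The urate transporter gene SLC2A9 had 0 UMIs against 445 CPM, 24.0-fold lower by the same measure (exact lower limit 18.5). slc23a4, chosen after its values were seen, was abundant in both classes, at 2036 and 2024 CPM against 1244 CPM. Of 13 organelle biogenesis genes, hps3 and hps5 stood at 18.6 and 24.8 CPM in leucophore-like cells of run 1 against 157 and 170 CPM, and rab27a at 136 against 39.3 CPM; the list's median was −0.54 (percentile 52.4). Transport genes dync1li2 and adcy5 stood at 712 and 365 CPM against 249 and 157 CPM, with a median of 1.17 over 3 genes (percentile 93.9). The V-ATPase gene atp6v0a1a stood at 161 CPM against 0 UMIs, at least 4.10-fold higher, and cd63 at 248 against 13.1 CPM, the latter 1 UMI (ratio 18.9, 3.20 to 765). ctsba and lgmn stood at 68.1 and 173 CPM against 262 and 393 CPM.

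Regulator genes id3, id2a and zeb2b stood at 675, 142 and 309 CPM in leucophore-like cells of run 1 against 118, 39.3 and 118 CPM, with a list median of 1.32 (percentile 97.3). Immediate early and stress genes, which dissociation can induce, had a median of −1.05 (percentile 5.86), with jun at 217 and 136 CPM against 1833 CPM (8.46-fold lower in run 1, 5.81 to 12.6), and fosl1a, dusp1 and klf4 at 68.1, 30.9 and 6.19 CPM against 471, 170 and 131 CPM. Glycolysis genes gapdhs and gapdh stood at 192 and 0 CPM against 445 and 144 CPM and eno1a at 173 against 78.6 CPM, with a list median of −0.84. The medians for lysosomal hydrolases, oxidative phosphorylation, the vacuolar ATPase and ribosomal proteins were −0.22, −0.40, 0.54 and −0.10, with atp5if1b at 285 against 118 CPM. The median log2 ratio of the 750 genes with at least 10 UMIs in both sums was −0.43, so list medians are to be read against that shift.

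The other widest gaps had 0 to 2 UMIs on one side in run 1. TBC1D9, vwc2, tp53i11b, cax1 and tppp3 stood at 501, 322, 279, 334 and 266 CPM in leucophore-like cells against 0 UMIs, at least 12.8-fold, 8.19-fold, 7.09-fold, 8.51-fold and 6.78-fold higher, and zgc:91968, a leading gene of the cluster, at 1349 against 26.2 CPM, the latter 2 UMIs. CD9, nkx6.2 and features named apodb and zgc:153704 stood at 681, 628, 511 and 746 CPM in iridophore-like cells against 0 UMIs in leucophore-like cells, at least 36.7-fold, 33.8-fold, 27.5-fold and 40.2-fold lower. scdb, a fatty acid desaturase gene, stood at 498 against 6.19 CPM, the latter 1 UMI.

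Iridophore-like and xanthophore-like cells were compared in run 1 alone, again without a replicate check. Pteridine synthesis genes had lower levels in iridophore-like cells, with a median log2 ratio of −3.16 over 4 genes (−4.01 to −2.42, percentile 0.170), and so did lineage regulators, at −2.19 over 6 genes (percentile 0.470), and pigment organelle transport, at −1.57 over 5 genes (percentile 2.45). Organelle biogenesis genes had higher levels, at 1.60 over 11 genes (1.21 to 1.93, percentile 98.9). By at least 2-fold, 3 of the 4 pteridine genes, 4 of the 6 regulators and 4 of the 5 transport genes were lower, and 1 regulator was higher. Of the 11 biogenesis genes, 8 were higher and 1 lower by that measure. gch2 stood at 144 against 2343 CPM, paics at 1637 against 386 CPM, pnp4a at 2344 against 3.30 CPM and GPNMB at 1938 against 0.0972 CPM. The 5 de novo purine genes had a median between 0.74 and 1.89 by counting error (percentile 89.3). Medians for glycolysis, the vacuolar ATPase, lysosomal hydrolases, oxidative phosphorylation, ribosomal proteins and immediate early genes were 0.93, 0.24, 0.17, 0.03, −0.33 and 0.16, and that of the 994 genes with at least 10 UMIs in both sums was 0.54.

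Of the pigment classes in run 1, leucophore-like cells lay nearest to xanthophore-like cells. Across 3636 genes in run 1, Pearson's r of log2 CPM was 0.636 between leucophore-like and xanthophore-like sums (Spearman's rho 0.614), 0.453 between iridophore-like and xanthophore-like sums (0.416) and 0.372 between leucophore-like and iridophore-like sums (0.365). Over the 3332 genes not used for clustering the order was the same, at 0.666, 0.539 and 0.444. The leucophore-like sums of both runs gave 0.914, the keratinocyte-like sums 0.961 and the xanthophore-like sums 0.640. These 14 correlations per gene set run across genes, which are not independent replicates, and carry no p-value. Keratinocyte-like cells gave 0.526 with leucophore-like cells over all 3636 genes, above the 0.372 of iridophore-like cells. The same held over genes not used for clustering (0.528 against 0.444) and in sums thinned to the iridophore-like depth (0.582 against 0.574). Over the 2280 genes with a mean of at least 50 CPM the order turned, at 0.148 against 0.544. That mean was taken mostly over pigment sums. In run 2, with no iridophore-like sum, leucophore-like cells gave 0.494 with xanthophore-like and 0.543 with keratinocyte-like cells. Over genes not used for clustering these were 0.531 and 0.540. The order turned over genes with a mean of at least 50 CPM (0.665 against 0.172) and in thinned sums (0.654 against 0.581).

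No comparison with melanophore-like cells was possible, since no cluster took that name. The 8 cells with pmela in the xanthophore-like sum of run 2 were the nearest to it, with 46842 UMIs in all. In them pmela stood at 5892 CPM (exact Poisson interval 5217 to 6630), tyr, the tyrosinase gene, at 1622 CPM (1278 to 2031) and oca2 at 1196 CPM (903 to 1552), while gch2 had 0 UMIs. Leucophore-like cells held pmela at 0 and 0.381 CPM and tyr at 6.19 and 2.67 CPM. They shared other genes of the melanophore marker list with these cells, MLANA at 514 and 459 CPM against 6511 CPM and trpm1b at 1126 and 1345 CPM against 1324 CPM, but neither gene is particular to them, with MLANA at 299 CPM in xanthophore-like cells of run 1 and trpm1b at 1079 CPM there and 1466 CPM in iridophore-like cells. Nearer to a shared gene of these cells alone was slc24a5, at 99.0 and 109 CPM against 107 CPM (5 UMIs), with 0.194 CPM in xanthophore-like cells of run 1 and 0 UMIs in iridophore-like cells. zgc:91968, no marker of the list, stood at 1349 and 1534 CPM against 2690 CPM, with 8.16 CPM in xanthophore-like cells of run 1. All of these genes were chosen after their values were seen.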

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

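The tests on single genes and cells named here were chosen after the result was seen, while keeping doublets was an alternative fixed before the data were examined. The 5 clusters that stayed unnamed were not compared with any class, and entered only the fit of all classes, pooled as 1 class. They were flagged for that reason alone. Each held at least 9 of 4347 cells in run 1 and at least 3 of 556 cells in run 2. A cluster of 198 cells was led by CRABP1 and krt94 and held keratinocyte and fibroblast markers together, with krt94 at 9051 CPM, krt5 at 11036 CPM, col1a2 at 408 CPM and dcn at 340 CPM. A cluster of 72 cells held T cell genes (CD3D at 1123 CPM, gata3 at 504 CPM) with the thrombopoietin receptor gene mpl at 370 CPM. A cluster of 30 cells, led by kcnc3b, held the myelin and glia genes mbpb, mpz and erbb3b at 909, 436 and 418 CPM, but its median of 1134 UMIs was too low for a name. A cluster of 21 cells held the B cell genes cd79a and pax5 at 1463 and 269 CPM with cd74a and MPEG1 at 9718 and 847 CPM. A cluster of 15 cells was led by fabp6 and apoa1b, genes of gut epithelium, with epcam at 5977 CPM. No explanation was tested for these clusters.

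The 8 xanthophore-like cells of run 2 with pmela UMIs stand apart from the class they were clustered with, since 2 of 2222 cells of that class in run 1, or 0.0900%, held such a UMI. Only 2 of the 12 cells held more than 1 UMI of scarb1, and another cell held all of their top2a, mki67 and ddx4 UMIs. Among all classes of run 1, 5 cells held a pmela UMI. When doublets were kept, the xanthophore-like share of run 2 was 0.693% and a melanophore-like cluster appeared. It held 5 cells of run 2 (0.867%), of which 4 were among these 8, but also 98 cells of run 1 (2.18%), of which 1 held a pmela UMI, so its name does not settle what the 8 cells are. No test set this against a biological alternative, as the labels give 1 group.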

How the results depend on the processing

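The fits without single sums, the whole comparison with non-pigment classes, the priors and the thinned sums are tests chosen after the results were seen; the other alternatives were fixed before the data were examined. For leucophore-like minus xanthophore-like (225 higher, 316 lower), DESeq2 gave 98 and 121, no filter 132 higher, no replicate block 146 and 180, and centring of the runs 103 and 128. Sums of 1 run come from the same library, which is why the run was a block. Without xanthophore-like replicate 2 and with no replicate block 722 and 1153 were called, over 9842 genes tested in place of 3636. Leaving out a leucophore-like sum with all classes in one fit gave 97 to 177 higher and 98 to 157 lower; there the lone sum is assumed to vary like the other classes. Other settings stayed within 1.5 times.

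The purine salvage call by camera, an adjusted p of 0.00491 after Benjamini-Hochberg adjustment, was lost without a filter (0.0693), with centred runs (0.357), without leucophore-like replicate 1 (0.0897), with an estimated correlation (0.870), and without xanthophore-like replicate 2 in a fit of all classes (0.0573) or with no replicate block (0.441, median −0.16, with 6 higher and 3 lower of 17 members tested). The cell cycle call was lost under median-of-ratios scaling (0.0782), no replicate block (0.332), all classes (0.157), centred runs (0.357) and an estimated correlation (0.870); without a leucophore-like sum it ran from 0.0897 to 0.399, and without xanthophore-like replicate 2 it was 0.942 in a fit of all classes and 0.840 with no replicate block, where its median was 0.006635. Without that sum ribosomal protein genes turned lower (1.28e-14 with all classes, 0.00697 with no replicate block), as did immediate early genes (0.0191 with no replicate block). These use the preset correlation; with an estimated correlation the adjusted p was 0.628 and 0.898 for ribosomal protein genes and 0.898 for immediate early genes. ddx4 turned to 0.91 with centred runs. The cause was not tested, apart from the 1 cell of run 2 that holds all top2a, mki67 and ddx4 UMIs of that sum. Of 192 list and setting pairs, 174 kept the side of the threshold, but 18 of the 151 never past it had the other direction by camera. Of 224 pairs of list median and setting, 154 stayed within the spread between the runs, 68 moved beyond it and 2, of called lists, changed sign. For named genes, 318 of 489 gene and setting pairs kept the side of the threshold, 2 of the 33 never past it with the other direction; 93 lost and 3 gained the call, 1 reversed, and 74 are values of 1 run alone, which have no test. Resolution 1.5, lists left in clustering and doublets kept leave fewer than 10 xanthophore-like cells in run 2, and so does a minimum of 20 cells for that class, so these gave no test; leaving out a whole run gives none either.

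For leucophore-like minus non-pigment classes (748 higher, 550 lower), higher counts were 1553 without a filter, 1496 with a minimum of 20 cells, 1285 without macrophage-like and 1363 without mural-like cells, 1606 at resolution 0.5, 1542 with doublets kept and 1378 at a minimum of 1000 UMIs. Lower counts were 1056, 885, 1025 and 1060 at 20 cells, resolution 0.5, doublets kept and 1000 UMIs, and 354 with centred runs. Most of these test more genes. Without leucophore-like replicate 1 or 2, 829 and 545 were higher and 400 and 219 lower. Of 1042 named gene and setting pairs, 997 kept the call and 45 lost it, with none reversed; of 266 list and setting pairs by camera 7 lost and 9 gained the call, 5 of the 7 with an estimated correlation.

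The xanthophore-like share of run 1 was 48.6% at resolution 1.5, 47.7% with lists in clustering and 48.1% with doublets kept, when 2.18% of run 1 took the melanophore-like name. In run 2 the xanthophore-like share of 2.16% (12 cells) fell to 1.26% (7 cells) under each of the first 2 settings, and with doublets kept it was 0.693%, with 0.867% melanophore-like. Pearson's r moved by more than its counting error while its order held. Leucophore-like with xanthophore-like gave 0.666, 0.725 and 0.711 over genes not used for clustering, genes of 50 or more CPM and thinned sums, and 0.614 by Spearman. Leucophore-like with iridophore-like gave 0.444, 0.544, 0.574 and 0.365, and iridophore-like with xanthophore-like 0.539, 0.613, 0.602 and 0.416. The purine salvage median against iridophore-like cells was 6.02 with a prior of 1 CPM, 1.90 with 50 CPM and 4.81 without leucophore-like replicate 1. Depth limits the iridophore-like values of run 1, where 3 UMIs equal 39.3 CPM, and the xanthophore-like values of run 2, where they equal 37.8 CPM.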

Other observations

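All tests in this part, the comparison with non-pigment cells included, were chosen after the results were seen. Set against 5 non-pigment classes of the same runs (keratinocyte-like, fibroblast-like, T or NK cell-like, macrophage-like and mural-like), leucophore-like cells had 748 higher and 550 lower genes of 3575 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 8 genes tested for pigment organelle transport were higher, overall and adjusted over the list alone (median log2 fold change 2.86). Among them, mlpha, the melanophilin gene that links Rab27 to a myosin motor, stood at 130 and 195 CPM against 4.21 and 0 CPM, the means over the other classes. Of 17 genes for lysosome-related organelles, 10 were higher and 1 lower, overall and adjusted over the list alone; RAB27B stood at 272 and 334 CPM against 7.01 and 3.43 CPM, and GPR143, of melanosome biogenesis, at 111 and 78.9 CPM against 4.98 and 0 CPM. Of 14 vacuolar ATPase genes 9 were higher and none lower, overall and over the list alone, with atp6v0a1a at 161 and 170 CPM against 12.4 and 8.87 CPM. By camera with Benjamini-Hochberg adjustment these lists rose with adjusted p of 3.03e-05, 4.37e-04 and 0.00110, and adjusted p = 0.194, 0.194 and 0.499 with an estimated correlation. The regulator genes mitfb and zeb2b were higher, at log2 fold changes of 6.16 (SE 0.57) and 3.72 (SE 0.40), and tfap2a and prdm1a lower, at −7.23 (SE 1.55) and −6.19 (SE 1.24).

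In the same comparison, gch2, slc23a4, uraha, gda and paics were higher, at log2 fold changes of 7.62, 11.06, 8.55, 8.72 and 3.64. Immediate early genes were lower in 6 of 19 and higher in 1, overall and adjusted over the list alone, with fosl1a at 68.1 and 64.4 CPM against 1655 and 1931 CPM and egr1 at 12.4 and 11.8 CPM against 364 and 385 CPM; camera gave 0.0114 after Benjamini-Hochberg adjustment, and adjusted p = 0.499 with an estimated correlation. Ribosomal protein genes fell as a list by camera (Benjamini-Hochberg adjusted p = 2.13e-09; adjusted p = 0.509 with an estimated correlation), with 2 of 73 called lower, overall and adjusted over the list alone, and a median of −0.41. Lysosomal genes went both ways, 4 higher and 4 lower of 19 (4 and 6 adjusted over the list alone), with ctsf higher at 2.71 and ctsh lower at −7.43. The lists for de novo purine synthesis, purine salvage, one-carbon supply, pteridine synthesis, glycolysis, nucleobase transport, oxidative phosphorylation and regulators were not past the threshold, at camera adjusted p of 0.765, 0.213, 0.765, 0.314, 0.213, 0.997, 0.469 and 0.320 after Benjamini-Hochberg adjustment. Pentose phosphate and cell cycle genes had too few members tested.

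Leucophore-like and xanthophore-like cells lie almost wholly in different runs, so a difference between the libraries could stand behind the genes called between them. Over tested genes not used for clustering, the leucophore-like sum of run 1 correlated better with the leucophore-like sum of run 2 (Pearson's r across genes 0.909) than with the xanthophore-like sum of its own run (0.666), a difference of 0.243, and this held in 200 of 200 random draws of 12 of the 25 cells. The 25 cells are in the leucophore-like class because clustering placed them with those cells of run 2, and the draws reuse them. A better correlation with run 2 was thus favoured by the grouping, also over genes left out of clustering, so it cannot weigh a library effect. The leucophore-like and xanthophore-like sums of run 1 do share 1 library, so their difference is not one between libraries. How much the libraries add to the called genes stays open, and no biological explanation was tested, as the labels give 1 group.

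pnp4a, best known from iridophores, was seen in leucophore-like cells at 68.1 and 56.4 CPM, and RNA freed from iridophores could have brought it there. In that case 23 other abundant iridophore-like genes would stand near the level that the pnp4a count needs. Their median in leucophore-like cells of run 2 was 3.33% of that level, and 21 of the 23 lay below 50%. GPNMB would need 40.3 CPM and had 0 UMIs. The tables thus argue against iridophore RNA as the source, and no biological explanation was tested.

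slc24a5, a cation exchanger gene of melanosomes, stood at 99.0 and 109 CPM in leucophore-like cells against 0.194 CPM in xanthophore-like cells of run 1, and RNA of melanophores could be its source. The other abundant genes of the 8 cells with pmela had a median of 0.151% of the needed level in leucophore-like cells of run 2, with 8 of 9 below 50%. pmela would need 2588 CPM and stood at 0.381 CPM. The source cells held 5 slc24a5 UMIs, and the upper end of that count's interval was used. The tables argue against melanophore RNA, and no biological explanation was tested.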
